A study of Mus musculus with 12 samples.

How the data were processed

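The series holds 12 mouse microglia libraries in 3 groups of 4, treated for 6 h with 500 nM Hevin, 50 ng/mL LPS or Media. Per the labels' protocols, libraries were made from 100 ng of RNA with a stranded poly(A) kit and sequenced as pairs of 100 bp reads. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.39, Bowtie2 2.3.5.1, featureCounts, Subread 1.6.3, R 4.0.0, edgeR 3.30.3 and the genome build mm10, without the role or order of each. The authors deposited FPKM values in 1 table of 14541 genes by symbol, of which 22 have names turned into dates; the annotation, the filter behind these rows and the use of strand are not given in the sources used here. Groups and replicate numbers came from the sample titles.

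FPKM steps were used to recover whole reads. In each of the 14541 rows the values of all 12 libraries were whole multiples of what 1 read is worth, within 0.1 of a whole number. The recovery returned 100% of 2301 simulated rows exactly, up to a common divisor of the counts of a row. The values equal reads divided by gene length and by a library total times a scaling factor, and these factors differed by at most 0.00124% from trimmed mean of M-values factors computed from the recovered reads. The factors were 0.804 to 0.897 in LPS and 1.02 to 1.16 in Media and Hevin, so FPKM sums were higher in LPS, at 422173 ± 6273 against 324698 ± 5325 in Media. Depth, counted as recovered reads in the listed genes, was 18343996 to 27361665 per library.

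Genes with at least 1 FPKM in at least 4 libraries were kept (11242). The 3 comparisons were fitted together with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, and p-values were adjusted by Benjamini-Hochberg with 0.05 as threshold. Gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the 24 of 27 lists with at least 3 genes tested. The lymphocyte list had 1 gene tested, and the erythroid and mitochondrial lists had 0, so these 3 were not tested. Lists, groups, tests, the alternatives set in advance and the rule for named genes were set before the data were examined. On simulated data for Hevin against Media (11120 genes) the test recovered 22.4% of 1.5-fold, 91.0% of 2-fold and 100% of 4-fold changes and called 0.0458% of unchanged genes. For LPS against Media (11110 genes) these were 25.4%, 88.1%, 100% and 0.0733%. The simulated changes were placed only in genes with higher read counts. The spread was assumed and held no differences between replicate numbers, so recovery in lower genes was not tested.

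Named genes were the 15 with the largest positive and 10 with the largest negative log2 fold change for each treatment against Media, and 8 and 8 for Hevin against LPS, among called genes whose libraries did not overlap and whose mean was at least 5 FPKM in 1 group. Added were the 4 smallest p of each list, 6 genes of LPS sensing and Hevin, and the highest member of each list of other cell types. Unnamed gene models were skipped, and the text leaves out some genes the rule names. Some results are not reported here.

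The titles give each group the same numbers 1 to 4. The deposited column names join the libraries of a number under a further label, Group 4 for number 1 to Group 7 for number 4. Deviations from the group means correlated between libraries of the same number in all 12 pairs, from 0.230 to 0.784, so the numbers pair the libraries. The mean of -0.201 between different numbers largely follows from this, since deviations cancel within each group. The planned main model has no block, so its SEs and p-values also hold the differences between numbers. The value with the replicate number as a block is printed where it changes a call or a count by over 1.5 times.

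Alternatives set in advance were pseudocounts of 0.1 and 5, other filters, only both groups compared, no trend, upper quartile scaling, quantile normalization, the block, a minimum absolute log2 fold change of 1, leaving out each library, and camera with an estimated correlation or fry. Chosen after seeing the data were limma-voom on recovered reads, no scaling factors, fits within replicate numbers, leaving out number 2, and the split of controls by number. For the shared Media controls, unchanged groups were simulated 100 times by drawing all 12 libraries, controls included, around the Media mean. Gene positions come from GENCODE M21 on GRCm38, where all 119 genes followed across alternatives were found. Figures were drawn with matplotlib 3.10.9.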

Results

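Microglia, the resident macrophages of the brain, were isolated with magnetic beads against the surface protein CD11b from the forebrains of mouse pups aged 7 to 9 postnatal days. The cells were plated at 40000 to 80000 per well and treated for 6 h. One group received 500 nM recombinant Hevin, a protein secreted by astrocytes and encoded by Sparcl1. Another group received 50 ng/mL lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4. The third group received Media alone. Each group held 4 libraries, numbered 1 to 4, of poly(A)-selected, strand-marked RNA, and gene levels were given as FPKM, which relates reads to gene length and library size. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries. Whole reads recovered from the FPKM values cover only the listed genes. They put the depth at 18343996 to 27361665 reads per library, with 18343996 to 25910349 in Media, 21389784 to 27361665 in Hevin and 19395973 to 27263115 in LPS. Of 14541 genes listed, 11242 were tested. Values below are mean FPKM ± SD over 4 libraries, and log2 fold changes ± SE are on the log2(FPKM + 1) scale, which understates the change of low genes.

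The comparison of Hevin with Media asked how the astrocyte protein changes the microglial transcriptome. Among the named genes the largest rise on the log2(FPKM + 1) scale was in Pmepa1, whose product restrains TGF-β signalling. Pmepa1 stood at 3.34 ± 0.400 FPKM in Media and 43.6 ± 2.33 in Hevin (log2 fold change 3.36 ± 0.13, limma adjusted p = 3.51e-08). In the homeostatic microglia list 8 of 24 genes rose (camera adjusted p = 1.05e-08, but adjusted p = 0.415 with an estimated correlation), among them the fractalkine receptor gene Cx3cr1 from 14.2 ± 1.07 to 54.7 ± 15.1 FPKM and Olfml3 from 11.1 ± 2.85 to 38.7 ± 7.99. Genes that fell included Il1b, which encodes the cytokine interleukin 1β, from 164 ± 26.1 to 53.4 ± 21.7 FPKM, and the neutrophil-attracting chemokine gene Cxcl2 from 438 ± 128 to 105 ± 6.44. In all, 480 genes were higher and 349 lower at an adjusted p under 0.05. With the replicate number as a block the counts were 1210 higher and 1196 lower.

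**Figure D1:**
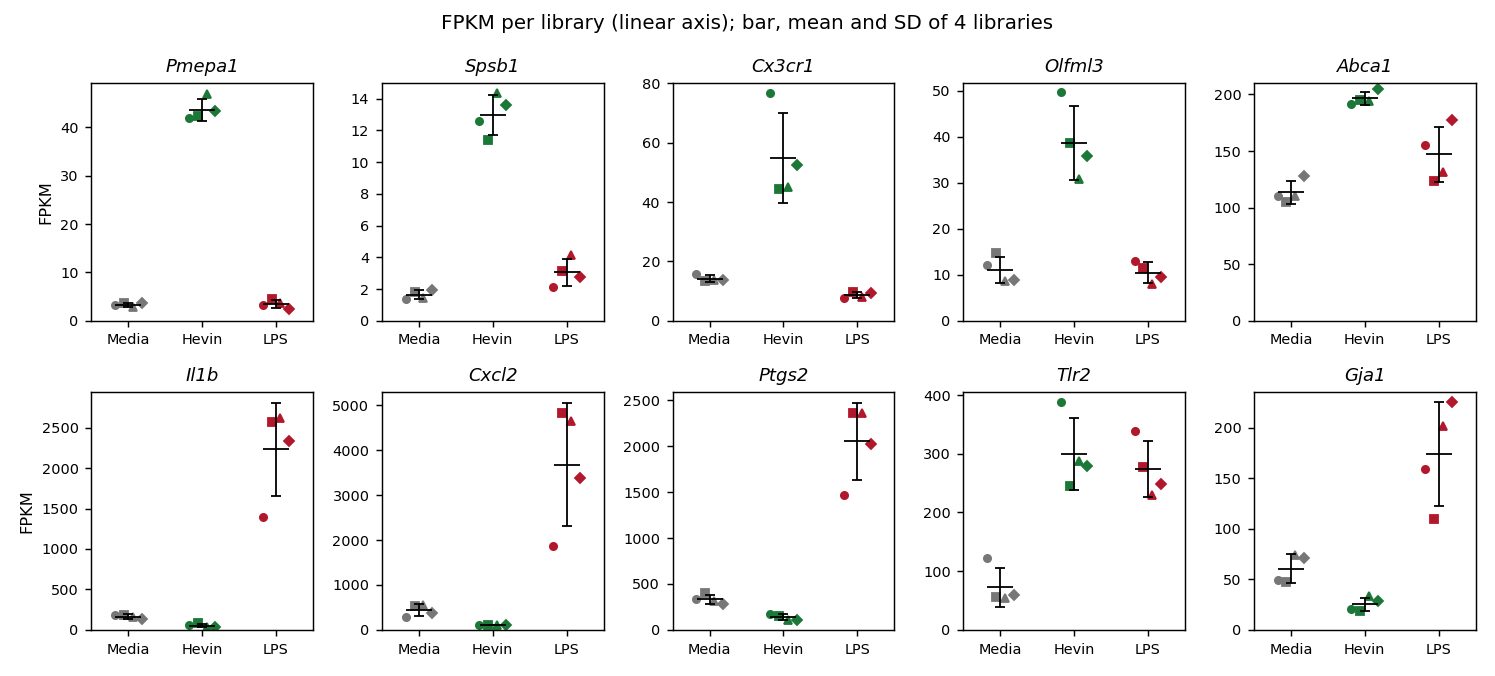
FPKM (linear axes) of 10 genes in the 12 libraries; circles, squares, triangles and diamonds mark replicate numbers 1, 2, 3 and 4, and bars show the mean and SD of 4 libraries. Pmepa1 averaged 43.6 FPKM in Hevin and 3.34 in Media, whereas Il1b averaged 53.4 in Hevin and 2231 in LPS.

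Another gene with a large rise in Hevin was the potassium channel gene Kcna3, from 0.861 ± 0.231 to 13.6 ± 0.921 FPKM. Gcnt1 rose by 2.80 ± 0.13, Pald1 by 2.59 ± 0.10, Spsb1 by 2.40 ± 0.15, Cpd by 2.33 ± 0.10, Elk3 by 2.16 ± 0.11 and H6pd by 2.19 ± 0.15 on the log2 scale. Arg1, the gene of arginase 1, rose from 0.658 ± 0.251 to 9.1 ± 4.31 FPKM, and the scavenger receptor gene Olr1 from 1.15 ± 0.549 to 10.3 ± 3.12. Ctla2a and Ctla2b also rose, but they are close paralogs and overlap other annotated exons on the same strand, so their separate values are uncertain. Among the named genes the largest falls on the log2 scale were in Serpinb2, from 16.4 ± 10.4 to 0.939 ± 0.661 FPKM, and in Csf3, the gene of a granulocyte growth factor, from 25.8 ± 21.5 to 2.64 ± 1.93. Both calls ended with voom on recovered reads without the block (adjusted p = 0.0526 and 0.0605), with adjusted p from 1.41e-06 to 0.169 for Serpinb2 and from 6.30e-08 to 0.102 for Csf3 over all alternatives. Calcrl, Cd300ld, the collagenase gene Mmp13 and Thbs1 had log2 fold changes of -1.75 ± 0.19, -1.69 ± 0.16, -1.62 ± 0.23 and -1.60 ± 0.12. Serpinb2 shares exonic sequence with Serpinb10 on the same strand, and Il1b with an annotated transcript on the opposite strand.

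Of the 24 homeostatic microglia genes tested, 0 fell and 11 rose when adjusted over the list alone, and with the block 17 rose and 1 fell. Besides Cx3cr1 and Olfml3 the members that rose included P2ry6, a nucleotide receptor gene, from 7.87 ± 0.961 to 42.5 ± 9.98 FPKM, and Fcrls, from 149 ± 12.4 to 277 ± 51.9. Among 9 targets of the sterol receptor LXR, 4 rose and 0 fell, with 6 rising when adjusted over the list alone and 7 with the block (camera adjusted p = 2.80e-04; adjusted p = 0.186 with an estimated correlation). Without Media 1, Media 2, Hevin 3 or Hevin 4 only 2 rose, and without the 3 libraries numbered 2 only 1. The cholesterol exporter gene Abca1 went from 113 ± 10.0 to 197 ± 5.83 FPKM, and Mylip, which promotes degradation of the LDL receptor, from 85.9 ± 18.8 to 152 ± 25.3. In the cell cycle list 3 of 19 genes rose, also when adjusted over the list alone, and 5 with the block (camera adjusted p = 6.24e-04; adjusted p = 0.504 with an estimated correlation). The replication helicase gene Mcm6 rose from 8.59 ± 0.503 to 16.4 ± 0.477 FPKM, whereas Mki67, a marker of cycling cells, stood at 9.91 ± 2.68 and 12.9 ± 3.12 FPKM and did not pass the test.

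Of 17 chemokine genes, 6 fell and 1 rose, 8 fell and 1 rose when adjusted over the list alone, and 11 fell and 1 rose with the block (camera adjusted p = 5.28e-04; adjusted p = 0.415 with an estimated correlation). Cxcl3 fell from 183 ± 20.7 to 72.4 ± 14 FPKM and Ccl4 from 461 ± 52.5 to 208 ± 35, while Cxcl16, which encodes a membrane-bound chemokine, rose from 34.3 ± 5.67 to 103 ± 15.1. In the list of NF-kB inhibitors, subunits and targets 4 of 17 fell and 0 rose, and 7 fell and 1 rose when adjusted over the list alone and likewise with the block (camera adjusted p = 2.80e-04; adjusted p = 0.415 with an estimated correlation). Without Hevin 2, Media 3, Hevin 4 or Media 4 only 2 fell, and 1 rose without Hevin 2. Ptgs2, the inducible prostaglandin synthase gene, fell from 335 ± 48.9 to 137 ± 33.1 FPKM and Traf1 from 17.6 ± 4.22 to 8.49 ± 1.37. Of 19 cytokine genes 3 fell and 0 rose, 6 fell when adjusted over the list alone, and 8 fell and 2 rose with the block (camera adjusted p = 0.0109; adjusted p = 0.496 with an estimated correlation). The number falling was 6 without LPS 1, 5 without Media 1 and 1 without the 3 libraries numbered 2. Tnf stood at 61.7 ± 9.11 FPKM in Media and 34.6 ± 5.39 in Hevin, with an adjusted p of 0.0664, or 0.0153 with the block. Il6, at 8.75 ± 5.67 and 2.71 ± 0.892 FPKM, had adjusted p values of 0.234 and 0.017 in the same order.

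Further lists that moved downward by camera were endoplasmic reticulum and heat stress, with 3 of 14 falling and 8 when adjusted over the list alone or with the block (adjusted p = 1.43e-03; adjusted p = 0.496 with an estimated correlation). Only 1 fell without Hevin 1, Media 2, Hevin 3, Media 3 or Hevin 4, and 5 without Media 1. Immediate early genes did so too, with 3 of 18 falling and 1 rising, 4 and 2 when adjusted over the list alone, and 11 and 2 with the block (adjusted p = 4.97e-03; adjusted p = 0.415 with an estimated correlation). Only 1 fell without Hevin 2, Hevin 3, Media 4 or the 3 libraries numbered 2, and 2 rose without LPS 2. In these lists Herpud1 fell from 48.3 ± 10.3 to 25.8 ± 3.01 FPKM and Btg2 from 92.8 ± 3.72 to 66.9 ± 2.5, while Fos rose from 53.5 ± 6.36 to 76.6 ± 7.64. In the NRF2 and oxidative stress list 2 of 14 fell, also when adjusted over the list alone, and 8 fell and 1 rose with the block (adjusted p = 8.32e-03; adjusted p = 0.415 with an estimated correlation). None fell without Media 1, Hevin 2, Hevin 3, Media 3, Hevin 4 or Media 4.

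None of the 32 interferon-stimulated genes passed limma's test over all genes or adjusted over the list alone, and 4 rose with the block; camera gave an adjusted p of 0.834. Camera called this list upward without Hevin 2 (adjusted p = 1.09e-03) and without the 3 libraries numbered 2 (0.0126, with 1 gene rising). The remaining biological lists did not pass camera. In the lists that did not pass, leaving out 1 library changed a count by at most 2 genes. Disease-associated microglia genes had 3 members higher and 1 lower of 22, or 6 and 3 when adjusted over the list alone, 7 and 4 with the block, 5 and 3 without LPS 1, 5 and 2 without LPS 3, and 1 and 1 without the 3 libraries numbered 2 (adjusted p = 0.179). Axl, a receptor for dying cells, rose from 22.4 ± 3.56 to 55.5 ± 8.85 FPKM, Trem2 from 71.9 ± 10.4 to 112 ± 14.6, and Lilrb4a, an inhibitory receptor gene, fell from 1516 ± 134 to 801 ± 162. Complement, phagocytic and scavenger receptors had 2 higher and 2 lower of 23, also when adjusted over the list alone, and 4 and 4 with the block (adjusted p = 0.988). C1qa rose from 162 ± 8.6 to 236 ± 30.3 FPKM and C5ar1 fell from 201 ± 15.8 to 107 ± 15.7. The alternative activation list split with 2 higher and 2 lower of 12, also when adjusted over the list alone (adjusted p = 0.988). Arg1 and Tgm2 rose, the latter from 16.1 ± 3.16 to 57 ± 14 FPKM, and the mannose receptor gene Mrc1 fell from 161 ± 16.8 to 71.7 ± 12. Glycolysis and hypoxia had 2 higher and 1 lower of 18 (adjusted p = 0.606), antigen presentation 1 lower of 19 (0.892), cholesterol synthesis 1 lower of 17 (0.476), and extracellular proteases 3 higher and 2 lower of 17 (0.988). Adjusted over the list alone these were 2 and 1, 1 and 1, 0 and 2, and 4 and 3, and with the block 2 and 2, 3 and 3, 0 and 3, and 5 and 6. Vegfa in the first of these rose from 21.9 ± 3.13 to 47.2 ± 6.02 FPKM.

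Toll-like receptors and adaptors had 1 member higher and 4 lower of 24 in Hevin, also when adjusted over the list alone, and 3 and 4 with the block (camera adjusted p = 0.688). Tlr2 rose from 72.6 ± 32.9 to 299.7 ± 61.7 FPKM, and Tlr1 and Ticam1 fell from 15.5 ± 1.43 to 7.79 ± 0.803 and from 29.8 ± 2.05 to 18.6 ± 0.972. Tlr4 went from 66.3 ± 7.03 to 48.1 ± 0.945 FPKM (log2 fold change -0.45 ± 0.11, limma adjusted p = 0.0326), a call that ended without any one of Hevin 1, 2, 3 or 4 or Media 1, 3 or 4, with adjusted p up to 0.0984. Over all alternatives the limma adjusted p of Tlr4 ranged from 4.70e-04 to 0.483. The LPS co-receptor genes Cd14 and Ly96 and the adaptor gene Myd88 did not pass, at log2 fold changes of -0.06 ± 0.09, -0.20 ± 0.20 and -0.18 ± 0.14. Sparcl1, the gene of Hevin itself, stood at 9.89 ± 5.5 FPKM in Media and 10.0 ± 6.11 in Hevin.

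The number of calls for Hevin against Media fell to 511 without Media 3 and to 532 without Hevin 4. Of the genes named above, the calls of Serpinb2, Csf3, Mylip, Trem2 and Ctla2a ended without the 3 libraries numbered 2, at adjusted p of 0.0581, 0.0820, 0.0647, 0.0719 and 0.0633. Over all alternatives the adjusted p of Mylip, Trem2 and Ctla2a reached 0.176, 0.235 and 0.0853. Within replicate numbers 1 and 2 alone 95 genes were called and within numbers 3 and 4 alone 1151, with 93 called in both. All 829 genes called had the same sign in both sets, which is partly by construction since they were chosen on the same libraries; among genes not called 69.7% did. No list passed camera with an estimated correlation, with or without the block. Median, mean and test differed in sign for the Toll-like receptor, complement, antigen presentation, alternative activation, protease, endothelial and border macrophage lists. None of these passed. For LPS against Media the signs differed for the glycolysis and neuron lists, and for Hevin against LPS for the neuron list.

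LPS served as the inflammatory reference. The acute phase gene Saa3 rose from 8.07 ± 2.04 FPKM in Media to 881 ± 554 in LPS (log2 fold change 6.37 ± 0.44, limma adjusted p = 1.15e-06), Il6 from 8.75 ± 5.67 to 421 ± 300.2, and Il1b from 164 ± 26.1 to 2231 ± 573. The chemokine genes Cxcl10 and Ccl5 reached 1690.3 ± 296 and 1269 ± 253 FPKM, from 38.6 ± 8.0 and 35 ± 28. Irg1, also named Acod1, which encodes the enzyme that makes itaconate, rose from 80.6 ± 28.2 to 2080.0 ± 248 FPKM. In all, 1484 genes were higher and 1413 lower, and 2416 and 2498 with the block. Ptges, Gbp5, Csf3, Rnd1, Ccrl2, Socs3, Slamf1, Il10, Cxcl1 and Il1a were also among the 15 largest rises, with log2 fold changes between 4.04 ± 0.33 and 5.43 ± 0.29. The falls were smaller. The platelet basic protein gene Ppbp went from 158 ± 37.8 to 31.3 ± 10.3 FPKM, and the transcription factor genes Hhex and Lyl1 from 15.6 ± 2.22 to 3.17 ± 1.55 and from 16.3 ± 2.58 to 4.1 ± 1.76. Hpgd, Dok2, Cytip, Arhgap25 and Nfam1 fell as well, with log2 fold changes of -2.03 ± 0.49, -1.99 ± 0.36, -1.87 ± 0.26, -1.82 ± 0.32 and -1.77 ± 0.24.

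All 17 genes of the NF-kB list rose in LPS, also when adjusted over the list alone (camera adjusted p = 4.49e-22; adjusted p = 0.0210 with an estimated correlation, 0.0609 with the block added). The inhibitor gene Tnfaip3 rose from 51.4 ± 5.95 to 650.0 ± 96.5 FPKM and Ptgs2 from 335 ± 48.9 to 2053 ± 420.5. Of 17 chemokine genes 16 rose by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 2.90e-15; adjusted p = 0.0278 with an estimated correlation, 0.0567 with the block added). Of 19 cytokine genes 13 rose, and 16 when adjusted over the list alone (camera adjusted p = 1.94e-11; adjusted p = 0.0339 with an estimated correlation, 0.0567 with the block added). Of 32 interferon-stimulated genes 19 rose, 22 when adjusted over the list alone, 32 with the block and 31 without the 3 libraries numbered 2 (camera adjusted p = 3.96e-11; adjusted p = 0.449 with an estimated correlation). Oasl1 rose from 155 ± 68 to 1463 ± 250.0 FPKM and Irf1 from 15.4 ± 2.61 to 58.6 ± 4.92. In the antigen presentation list 12 of 19 rose and 1 fell, or 13 and 1 when adjusted over the list alone (camera adjusted p = 3.17e-07; adjusted p = 0.0339 with an estimated correlation). None fell without LPS 1, LPS 2, Media 2, LPS 3, Media 3, Media 4 or the 3 libraries numbered 2. H2-K1 went from 204 ± 25.3 to 395 ± 43.1 FPKM, Cd40 from 3.11 ± 1.9 to 24.3 ± 9.48 and Cd274 from 17 ± 2.32 to 156 ± 45.6.

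The following 4 lists were also higher in LPS by camera with the preset correlation, but not with an estimated correlation. They were immediate early genes, proteases, NRF2 and alternative activation. Fry called these lists upward too, with adjusted p of 2.01e-04, 2.90e-07, 2.66e-04 and 6.10e-05 in the same order. Of the immediate early genes 8 of 18 were higher and 2 lower (adjusted p = 3.54e-03; adjusted p = 0.258 with an estimated correlation). Of the extracellular proteases and inhibitors 7 of 17 were higher and 2 lower (adjusted p = 0.0123; adjusted p = 0.0575 with an estimated correlation). In the NRF2 and oxidative stress list 7 of 14 were higher and 2 lower (adjusted p = 0.0174; adjusted p = 0.397 with an estimated correlation). In the alternative activation list 5 of 12 were higher (adjusted p = 0.0174; adjusted p = 0.180 with an estimated correlation). Adjusted over the list alone the counts were 9 and 2, 7 and 2, 8 and 3, and 6 and 1. With the block 11 and 3 of the protease genes, 8 and 4 of the NRF2 genes and 7 and 2 of the alternative activation genes were higher and lower. Mmp14 rose from 17.9 ± 4.85 to 168 ± 28.4 FPKM, Sod2 from 49.5 ± 10.2 to 299.9 ± 44.1 and Slc7a11 from 224 ± 32.1 to 607 ± 44.8, whereas Nqo1 fell from 121 ± 7.44 to 65.9 ± 6.87. The direction of the NRF2 list turned under quantile normalization, and its camera call ended without LPS 1 (adjusted p = 0.0537). Of the immediate early genes only 1 was lower without Media 1, Media 2, LPS 3, LPS 4, Media 4 or the 3 libraries numbered 2. In the alternative activation list 1 was lower without Media 1, LPS 2 or LPS 3. Toll-like receptors and adaptors had 10 higher and 6 lower of 24, or 11 and 7 when adjusted over the list alone, and 3 lower without Media 1 (camera adjusted p = 0.138). Cd14 rose from 2267 ± 86.6 to 4712 ± 454 FPKM, although not under quantile normalization (adjusted p = 0.903, the highest over all alternatives), Myd88 by 1.04 ± 0.14 and Tlr2 by 1.97 ± 0.24 on the log2 scale, and Ticam2 fell from 12.6 ± 1.74 to 3.76 ± 0.875 FPKM. Tlr4 was also called lower in LPS, at 40.5 to 59.3 FPKM against 58.0 to 73.8 in Media. That call ended without Media 1, LPS 2, LPS 3 or Media 4, and its limma adjusted p reached 0.238 over all alternatives. Homeostatic genes had 1 higher and 3 lower of 24, also when adjusted over the list alone, 3 and 6 with the block, and 5 lower without LPS 1 (camera adjusted p = 0.509), with Cx3cr1 at 8.68 ± 0.980 FPKM and Mef2c falling from 19 ± 5.7 to 4.98 ± 1.81. The 1 higher was P2ry6, which also rose in Hevin, at 11.2 to 17.1 FPKM in the LPS libraries and 6.88 to 9.16 in Media.

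The other lists did not pass camera for LPS. In the lists that did not pass, leaving out 1 library changed a count by at most 3 genes. Disease-associated microglia genes had 3 higher and 6 lower of 22 (adjusted p = 0.566), complement and scavenger receptors 5 and 3 of 23 (0.630), glycolysis and hypoxia 4 and 2 of 18 (0.538), cholesterol synthesis 0 and 1 of 17 (0.777), LXR targets 1 and 1 of 9 (0.865). The cell cycle list had 1 and 1 of 19 (0.566), and endoplasmic reticulum and heat stress 3 and 2 of 14 (0.560). Adjusted over the list alone they had 3 and 7, 5 and 4, 4 and 2, 0 and 0, 1 and 1, 1 and 1, and 3 and 3. With the block complement and scavenger receptors had 9 higher and 7 lower, cholesterol synthesis 2 and 3, LXR targets 2 and 2, cell cycle 1 and 4, and stress genes 6 and 3. In the cell cycle list Mki67 rose from 9.91 ± 2.68 to 32.6 ± 9.82 FPKM and Cdk1 fell from 3.96 ± 0.722 to 1.86 ± 0.570. The scaling between libraries bears on the lower calls: upper quartile scaling gave 1136 higher and 2466 lower genes, and no scaling gave 736 higher and 4990 lower, with the median of all genes at -0.29 on the log2 scale. Within numbers 1 and 2 alone 527 genes were called and within numbers 3 and 4 alone 3400.

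**Figure D2:**
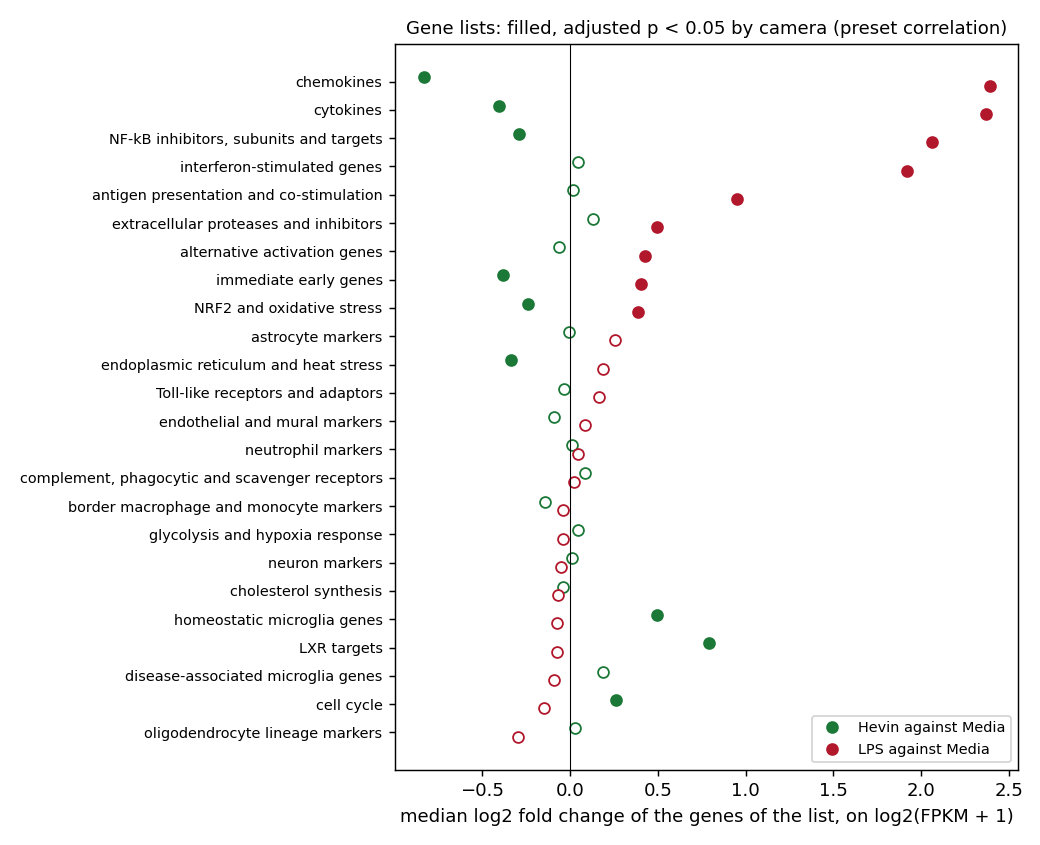
Median log2 fold change on log2(FPKM + 1) of the genes of each of 24 lists for Hevin (green) and LPS (red) against Media; filled points passed camera with the preset correlation. The chemokine list stood at a median of -0.83 in Hevin and 2.39 in LPS.

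Hevin was then compared with LPS directly, which tests whether the responses differ. Csf3 and Cxcl2 were lower in Hevin: Csf3 averaged 2.64 ± 1.93 FPKM against 608 ± 320.0 in LPS (log2 fold change -7.34 ± 0.57, limma adjusted p = 1.40e-06), and Cxcl2 105 ± 6.44 against 3680.1 ± 1371. Gcnt1 was higher in Hevin at 34.5 ± 5.24 against 1.24 ± 0.335 FPKM, Elk3 at 39.1 ± 3.97 against 3.9 ± 0.648 and Il21r, a cytokine receptor gene, at 20.9 ± 4.09 against 1.55 ± 0.600. In all 2470 genes were higher and 2215 lower in Hevin than in LPS. With no scaling the split was 5398 higher and 971 lower, and with upper quartile scaling 3437 higher and 1643 lower.

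In this comparison all 17 NF-kB genes were lower in Hevin, also when adjusted over the list alone (camera adjusted p = 1.47e-17; adjusted p = 0.0403 with an estimated correlation), as were 16 of 17 chemokine genes, also when adjusted over the list alone (1.43e-13; adjusted p = 0.0403 with an estimated correlation). With the block added both estimated-correlation values were an adjusted p of 0.0750. Of 19 cytokine genes 15 were lower and 1 higher (8.74e-09; adjusted p = 0.0640 with an estimated correlation), of 32 interferon-stimulated genes 17 were lower (1.90e-07; 0.527), and of 19 antigen presentation genes 12 were lower (2.93e-06; 0.0640, or 0.0164 with the block), the bracketed values being adjusted p with the preset and the estimated correlation. Adjusted over the list alone 15 and 1, 21, and 13 passed, and with the block 31 interferon-stimulated and 19 antigen presentation genes were lower. Homeostatic genes were higher in Hevin for 15 of 24 and lower for 0 (2.43e-05; 0.370), LXR targets for 6 of 9 (0.0192; 0.238) and cell cycle genes for 8 of 19 with 1 lower (0.0145; 0.527). Immediate early genes were lower for 11 of 18 with 2 higher (4.66e-04; 0.223), NRF2 genes for 9 of 14 with 3 higher (6.29e-03; 0.273) and stress genes for 5 of 14 with 1 higher (0.0341; 0.527). Adjusted over the list alone these 6 lists had 16, 6, 9 and 1, 11 and 2, 9 and 3, and 5 and 1. With the block 13 cell cycle genes were higher and 1 lower, and 9 stress genes lower and 2 higher. The camera call of the cell cycle list ended without LPS 1 (adjusted p = 0.0652), and 13 of its genes were higher without LPS 2. The call of the stress list ended without Hevin 1 (0.0799) and without LPS 2 (0.0906). Under quantile normalization the direction of the NRF2 list turned. Without the 3 libraries numbered 2, 29 interferon-stimulated genes were lower, and without Hevin 4 only 1 immediate early gene was higher. Toll-like receptors (adjusted p = 0.138), disease-associated (0.170), complement (0.643), glycolysis (0.484), cholesterol synthesis (0.771), protease (0.128) and alternative activation (0.121) lists did not pass camera. The first 3 had 5 higher and 11 lower of 24, 7 and 2 of 22, and 5 and 7 of 23. Glycolysis had 3 and 6 of 18, cholesterol synthesis 3 and 3 of 17, and protease 3 and 7 of 17. Alternative activation had 2 and 6 of 12. With the block Toll-like receptors had 9 and 11, complement 8 and 9 and cholesterol synthesis 5 and 6. Protease then had 5 and 8 and alternative activation 4 and 8. Fry called all but complement (adjusted p = 0.358) and cholesterol synthesis (0.817). Tlr2, at 299.7 ± 61.7 FPKM in Hevin and 274 ± 47.5 in LPS, had a log2 difference of 0.13 ± 0.24 (limma adjusted p = 0.719), and Axl a difference of 0.13 ± 0.14 (limma adjusted p = 0.506).

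The log2 fold changes of Hevin and of LPS against Media had a Pearson correlation of -0.14 across 11242 genes, which are not independent replicates. Its jackknife SE over the 12 libraries was 0.108. Leaving out 1 library gave -0.19 to -0.05, with -0.05 without Media 3 and -0.083 without Media 1. Both comparisons share the Media libraries. In 100 simulations with no effect, in which all 12 libraries were drawn anew, the shared controls alone gave a mean correlation of 0.50. The observed covariance was -0.0269 against a simulated 0.0212, or 0.00707 when the spread left by the replicate block was used, and the differences were -0.0481 and -0.0339. With the Media libraries split 2 and 2 between the comparisons the correlation averaged -0.23 over 6 splits. Differences between replicate numbers do not cancel in that split. Where each comparison used its own 2 numbers and no library was shared, the correlation averaged -0.17, with a range of -0.20 to -0.14, and the covariance -0.0342.

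Of the genes called in both comparisons, 71 were higher in both and 80 lower in both, while 144 were higher in Hevin and lower in LPS and 137 lower in Hevin and higher in LPS. Independent lists of these sizes would share 63.4, 43.9, 60.3 and 46.1 genes. The simulations with no effect shared 0, but data without an effect give few calls. They therefore set no reference for the overlap of treatments that have effects. With split controls the averages were 32.5, 27.5, 59.7 and 64.0, and with the block 229, 281, 439 and 468. Leaving out Media 3 gave 41, 43, 91 and 79, and leaving out LPS 2 gave 78, 81, 146 and 144. The counts also depended on the scaling: without scaling factors they were 51, 163, 381 and 87, with upper quartile scaling 62, 127, 246 and 127, and with quantile normalization 66, 131, 182 and 114. Of the 1484 genes higher in LPS, 9.23% were called lower in Hevin and 4.78% higher. With the block 2416 genes were higher in LPS, of which 468 were called lower in Hevin and 229 higher. Among the 71 genes higher in both, Hevin was above LPS for 20, LPS above Hevin for 19, and the difference was not called for 32. Cpd, Olr1, Tgm2, Axl, Cxcl16, Tlr2 and P2ry6 were among these 71 genes. Ppbp, Cd300ld, Dok2 and Tlr4 were among the 80 genes lower in both. The calls of Dok2 in Hevin and of Tlr4 in both treatments ended when some single libraries were left out.

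**Figure D3:**
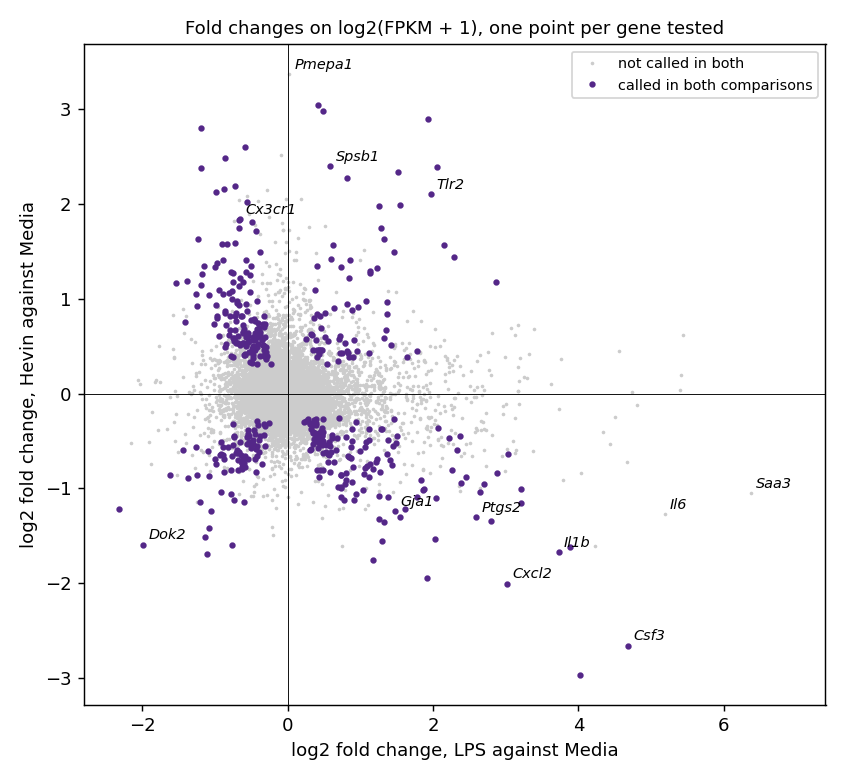
Log2 fold change on log2(FPKM + 1) against Media for LPS (horizontal) and Hevin (vertical), 1 point per gene tested; purple points were called in both comparisons. The correlation was -0.14, and 137 genes lay lower in Hevin and higher in LPS.

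Libraries also differed by replicate number. The first principal component held 50.2% of the variance and the second 18.8%, and the second separated numbers 1 and 2 from 3 and 4. The neutrophil gene S100a9 averaged 862 ± 89.9 FPKM in the 3 libraries numbered 2 and 26.6 to 30.3 in the other numbers (n = 3 each). The astrocyte-rich transcript Clu averaged 4.28 ± 0.935, 13.3 ± 4.19, 36.01 ± 5.72 and 28.7 ± 4.28 FPKM in numbers 1 to 4, the endothelial gene Cldn5 6.56 ± 1.56, 19.9 ± 2.05, 50.4 ± 6.93 and 30.6 ± 4.72, and the neuronal gene Tubb3 1.01 ± 0.118, 1.58 ± 0.622, 5.14 ± 0.811 and 2.65 ± 0.610. Ttr averaged 202 ± 26.4, 827 ± 275, 2312 ± 338 and 1659 ± 202 FPKM in the same order. Ptgds averaged 4.31 ± 1.84, 3.96 ± 1.83, 48.4 ± 18.1 and 26.6 ± 4.67. Both genes are in none of the lists, and which cells they came from was not tested. Between treatments neuron, endothelial and neutrophil markers had 0, 0 and 0 genes called of 9, 12 and 11 for Hevin and 0, 0 and 1 for LPS, where Csf3r rose from 7.47 ± 2.56 to 23.9 ± 6.31 FPKM. With the block these were 0, 1 and 1 for Hevin and 0, 1 and 4 for LPS. Their camera adjusted p values, in the same order, were 0.988, 0.988 and 0.935 in Hevin and 0.890, 0.795 and 0.622 in LPS.

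Of 7 astrocyte markers the connexin gene Gja1 was the one called: it fell from 60.7 ± 14 to 25.3 ± 6.61 FPKM in Hevin and rose to 174 ± 51.1 in LPS (list adjusted p = 0.588 and 0.509). With the block 3 astrocyte markers rose in LPS. Among 5 oligodendrocyte lineage markers Cspg4 rose in Hevin from 2.72 ± 1.24 to 20.1 ± 8.1 FPKM and Mbp fell in LPS from 8.16 ± 1.7 to 4.2 ± 1.49 (list adjusted p = 0.476 and 0.271). Cspg4 also fell in LPS, to 0.981 ± 0.332 FPKM (limma adjusted p = 0.0458, or 2.90e-04 with the block), a call that ended without any one of LPS 1, 2, 3 or 4 or Media 3 or 4 and whose adjusted p reached 0.208 over all alternatives. Of 11 border macrophage and monocyte markers 3 were higher in Hevin, or 1 without Media 1 or Hevin 4, among them Ms4a7 from 20.5 ± 2.87 to 39.1 ± 3.18 FPKM, while Pf4 stood at 583 ± 50.1 and 484 ± 76.2 (limma adjusted p = 0.219, or 0.0341 with the block). In LPS 1 was higher and 1 lower, and with the block 4 were higher and 3 lower in Hevin and 3 and 4 in LPS (list adjusted p = 0.832 in Hevin and 0.566 in LPS). For Hevin against LPS the astrocyte, neuron, oligodendrocyte, endothelial, border macrophage and neutrophil lists had adjusted p values of 0.324, 0.952, 0.128, 0.802, 0.484 and 0.739. Without the 3 libraries numbered 2 the calls were 594 for Hevin against Media, 2642 for LPS against Media and 4290 for Hevin against LPS.

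**Figure D4:**
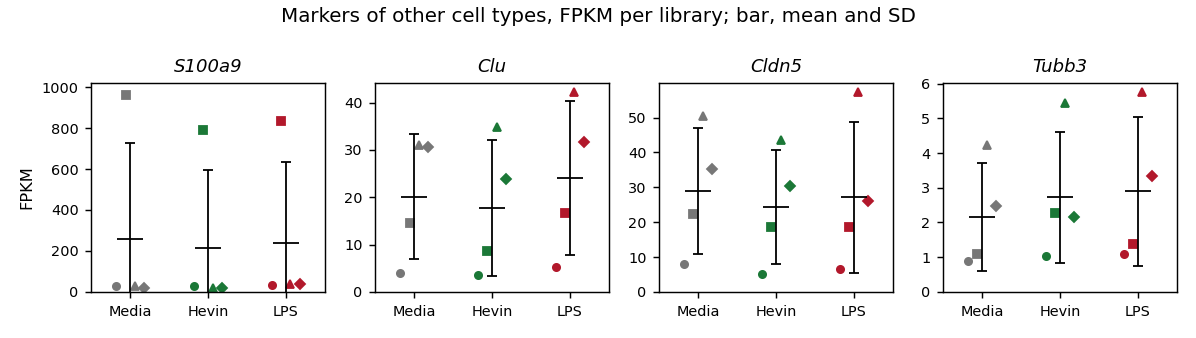
FPKM (linear axes) of markers of neutrophils (S100a9), astrocytes (Clu), endothelium (Cldn5) and neurons (Tubb3) in the 12 libraries; circles, squares, triangles and diamonds mark replicate numbers 1, 2, 3 and 4, and bars show the mean and SD of 4 libraries. The S100a9 bars are cut off at 0, and S100a9 averaged 862 FPKM in the 3 libraries numbered 2.

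In the mouse genome build GRCm38 (mm10) all genes placed here are protein coding. Pmepa1 lies on chromosome 2 from 173224458 to 173276533, Cx3cr1 on chromosome 9 from 119901616 to 120069879, Olfml3 on chromosome 3 from 103722222 to 103738001, Il1b on chromosome 2 from 129364570 to 129371139, Cxcl2 on chromosome 5 from 90903871 to 90905938, Tlr2 on chromosome 3 from 83836272 to 83841767, Saa3 on chromosome 7 from 46711998 to 46715700 and Gja1 on chromosome 10 from 56377330 to 56402513. Exons of Ticam2 overlap exons of Tmed7 and those of Lilrb4a exons of Gm49339, on the same strand in both cases, so these 2 values are uncertain. Exons of Cx3cr1, Spsb1, Thbs1, Elk3, Cxcl10, Cxcl16, Tgm2, Myd88, Cd274, Il1a, Irf1, Lyl1, Oasl1 and Lilrb4a overlap exons of another gene on the opposite strand, and whether the authors' counting used strand is not given in the sources used here, so their values may hold reads of both.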

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

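The tests of endotoxin, of the scaling factors and of an astrocyte share in these parts were chosen after the results were seen. In 21 of 357 sets of 4 libraries (119 genes in 3 groups), 1 library stood apart from the other 3 by more than Dixon's 95% critical value on the log2 scale. Chance gives about 1 in 20 such sets.

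S100a9 was far higher in the libraries numbered 2 of all 3 groups, at 962 FPKM in Media, 789 in Hevin and 835 in LPS, against at most 39.5 in the others. Ifit3 was 120 FPKM in LPS 2 against at least 363, and Oasl1 was 1088 in LPS 2 against at least 1585. Also in number 2, Socs3 was 259 FPKM in LPS, Axl 42.3 and H2-K1 172 in Hevin, and Nfkbia 87.1 and Mmp14 10.8 in Media, each below the other 3. Above the other 3 were Thbs1 at 480 in Media 2, Mcm7 at 3.92 in Hevin 2 and Ddit3 at 104 in Hevin 2.

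In number 1, Olr1 was 2.69 FPKM in LPS 1 against at least 10.4 in the other LPS libraries, Saa3 was 1.22 in Hevin 1 against at least 4.02, Tlr2 was 122 in Media 1 against at most 58.8, Lilrb4a was 1042 in Hevin 1 against at most 747, and Il21r was 2.45 in LPS 1 against at most 1.29. Smaller gaps were Tlr4 at 46.7 FPKM in Hevin 3, Arg1 at 1.03 in Media 4 and Mcm6 at 7.84 in Media 4.

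Libraries with the same replicate number deviated together, which is the pattern weighed here. Depth as the whole cause is argued against: after thinning every library to the smallest depth, the lowest of the 12 same-number correlations was 0.229. Different shares of other cell types as the whole cause are argued against by 69 genes of the microglial lists, over which the lowest of these correlations was 0.408, and by the 24 homeostatic genes alone, a check added because the other lists hold genes of other myeloid cells, where it was 0.308. Some genes of these lists are also expressed by other cells, so this check alone does not settle it. Other cell types may still make up part of the pattern, as S100a9 and Clu show. Litter, day and animal stay open as untested.

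Gja1 fell with Hevin and rose with LPS. A different share of astrocytes is argued against, since the median log2 fold change of the other 6 astrocyte markers was -0.0030 in Hevin and 0.22 in LPS (SD 0.13 and 0.17), against -1.24 and 1.48 for Gja1. Expression of Gja1 in the microglia, or a change within the astrocytes present, stays open.

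Splits of the 8 libraries could not decide whether chance gave the counts of calls. Over splits that ignore the pairing, only the real split of 35 gave as many genes. The real counts were 829 for Hevin against Media, 2897 for LPS against Media and 4685 for Hevin against LPS. The highest other count was 0 in each comparison. Of the 8 splits that part all 4 numbered pairs, the other 7 gave 0 as well, but 8 splits are too few for a share under 12.5%. These 7 differ from the real split in mixing treated and control libraries in both sets, which widens the spread within sets.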

How the results depend on the processing

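Fits within replicate numbers, without scaling factors, with voom, and the estimated correlation or fry combined with the block were chosen after seeing the data. With the replicate block the calls rose to 2406 for Hevin against Media and 4914 for LPS against Media, and the same-direction overlap from 151 to 510; all 829, 2897 and 4685 genes called without the block were kept with the same sign. Voom on recovered reads with the block gave 2729 and 4957 calls and an overlap of 616. A minimum absolute log2 fold change of 1 left 185, 601 and 954 calls in the 3 comparisons and an overlap of 22, by construction. Numbers 1 and 2 alone gave 95, 527 and 1516 calls and an overlap of 13; numbers 3 and 4 alone gave 1151, 3400 and 5103 calls and an overlap of 258. No scaling factors gave 5726 calls for LPS against Media, and the median of all genes stood at -0.29, or at -0.12 with upper quartile scaling, against -0.024 in the main fit. Splitting the Media libraries 2 and 2 left an overlap of 60.

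Leaving out 1 library gave 511 to 930 calls for Hevin against Media, 2164 to 2869 for LPS against Media and 3865 to 4702 for Hevin against LPS. The same-direction overlap ranged from 84 to 159, with 84 without Media 3, 90 without Media 4 and 99 without Hevin 4. Calls in opposite directions numbered 281 in the main fit, 170 without Media 3 and 297 without LPS 1. The correlation ranged from -0.19 to -0.05. The number of lists called ranged from 9 to 10, 8 to 9 and 10 to 11. With an estimated correlation 0, 4 and 2 lists passed camera instead of 9, 9 and 11, and with the block added 0, 1 and 1; fry gave 7, 12 and 18, and with the block 12, 16 and 19. For Hevin against Media fry did not call the cytokine (adjusted p = 0.104), cell cycle (0.0944) and stress (0.0944) lists and called oligodendrocyte markers (0.0423). Camera and fry ask different questions. No camera call with the preset correlation changed with the block.

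Over 119 genes and both comparisons with Media, 94.1% of 6414 values kept their side of the threshold and their direction, 293 were no longer called, 83 became called and 4 reversed, all under quantile normalization for LPS against Media: Fcrls (-0.34), Prdx1 (-0.20), Abca1 (-0.081) and Atf4 (-0.34). For lists 94.6% of 2229 did, 73 were lost, 45 gained and 2 reversed: the NRF2 list had a median of -0.14 for LPS against Media and 0.015 for Hevin against LPS under quantile normalization. Both shares are partly by construction, since the alternatives reuse these libraries. The 119 genes were also named largely by their values in them. Where no construction is named, the cause was not tested. At the depth of these libraries and an assumed spread, 22.4% of simulated 1.5-fold changes were recovered for Hevin against Media. These changes were in genes with higher read counts only, and depth was not varied.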

Other observations

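The tests of endotoxin and of the scaling factors were chosen after the result was seen. The test of the list of TGF-β signalling genes was set before its values were seen. Several genes that rose in Hevin are known as direct targets or feedback regulators of TGF-β signalling. All of those named in this paragraph, Pmepa1 and Spsb1 included, were chosen after their values were seen and are no independent evidence. Skil rose from 26.8 ± 4.87 to 108 ± 11.5 FPKM, Smad7 from 4.23 ± 1.44 to 16.4 ± 3.16, Ldlrad4 from 5.16 ± 2.41 to 19.2 ± 5.33, Tgfbi from 19.2 ± 2.85 to 84.7 ± 22.9 and the receptor gene Tgfbr1 from 62.1 ± 18 to 196 ± 60.5 (SD, n = 4 each). In LPS these were 79.8 ± 13.9, 6.43 ± 2.01, 6.59 ± 3.27, 19.1 ± 3.23 and 70.7 ± 27.7 FPKM.

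Genes raised by LPS stood lower on balance with Hevin. Of 482 genes that LPS raised by at least 1 on the log2 scale, 61.2% had a negative log2 fold change in Hevin, with a median of -0.11; 61 were called lower and 24 higher, or 137 and 66 with the block. The test of residual endotoxin in the Hevin preparation set this median against the SD of 0.61 over these genes and could not tell. That SD measures how the genes differ, not how well their median is known. In the 4 numbers the median was -0.10, -0.15, -0.13 and -0.097 (SD 0.024), so these genes did not rise on balance in any number. The genes went both ways, so a rise from endotoxin outweighed by other falls cannot be told from this. The authors' scaling factors as the whole cause are argued against, since without them the median was -0.0957, and -0.10, -0.13, -0.079 and -0.078 in the 4 numbers.

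A candidate explanation for the Hevin profile is a TGF-β type response. A list of 30 genes, SMAD targets together with other genes of TGF-β signalling such as Tgfb1, Smurf1 and Itgav, left out the genes above. It had 24 genes tested and a median log2 fold change of 0.29 in Hevin, at percentile 100 of 10000 random lists matched on mean FPKM (95% of them between -0.12 and 0.092). Camera gave p = 7.24e-03 with the preset correlation, but p = 0.128 with an estimated correlation and p = 0.11 with the block added. Of the 24 genes 5 were called higher, or 11 with the block, among them Ski from 21.7 ± 2.28 to 50.2 ± 4.29 FPKM and Itgav from 34.4 ± 6.20 to 86.2 ± 12, and 1 was called lower with or without the block, Cdkn2b, itself a known TGF-β target, from 8.20 ± 0.795 to 4.13 ± 0.861. Ctgf, Bambi, Tsc22d1 and Cdkn1a were among those not called, at log2 fold changes of 0.096, 0.17, 0.051 and -0.20 in Hevin. The list's median was also positive in LPS, at 0.20, and the difference between the treatments was not tested for this list. Whether Hevin itself, a factor carried with the recombinant protein or another route is behind it was not tested.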
